A study of Rattus norvegicus with 6 samples.

How the data were processed

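Total RNA of NRK-52E cells, an epithelial line from rat kidney tubules, was measured on 6 arrays, 3 of control cells and 3 of cells overexpressing the intracellular domain of Notch1 (NICD1), and groups and replicate numbers were taken from the sample titles. The RNA was carried into biotin-labelled, fragmented cDNA with Affymetrix whole-transcript kits, per the labels' protocols. The deposited values are RMA intensity values, 1 per probe set and array, made with Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalises quantiles between arrays and summarises probes into probe sets, so a shift shared by most transcripts would be removed before any comparison. The array type, the genome build and the software versions are not given in the sources used here. The deposited intensity values were on a linear scale, with array medians from 57.5 to 60.1, so log2 was taken with no pseudocount. The number of arrays, 3 per group, limits the precision.

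Of 36685 probe sets, 18511 had 1 gene symbol in the platform annotation, 575 had several and 17599 had none. Of the 18511, 18394 had a gene identifier found in the rat reference annotation (GRCr8), which changed 0 symbols. That annotation was used for names and gene order only. Probe sets with 1 symbol were averaged per symbol on each array, which gave 18166 genes. Of 291 genes with several probe sets, 0 had probe sets called in opposite directions, and 13 had only some called. Probe sets with several symbols or none entered no gene value. The file gives no detection call. A background level was therefore taken as the 95th percentile of the mean log2 intensity of 1343 chemosensory receptor genes, 5.74, after the data were seen. It was used to describe levels and removed no gene.

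The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on log2 intensity with the group as the single term, two-sided. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Fold changes are NICD1 minus control. All adjusted p-values of single genes come from this limma fit. For Notch1 an exact permutation test over the 20 arrangements was added. 23 gene lists were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and adjustment over the lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance without comparing it with other genes, were alternatives. The lists were Notch targets, Notch pathway components, mesenchymal and matrix genes, epithelial junction genes, proximal tubule genes, tubule injury and repair genes, cell cycle genes, p53 targets with CDK inhibitors, inflammation, interferon response, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein and amino acid response, NRF2 targets, Wnt targets, TGF-beta, BMP and Hippo targets, ribosomal proteins, and markers of leukocytes, endothelium, podocytes, distal nephron, and fibroblasts with pericytes. List members without a value are not analysed here.

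The groups, tests, lists, rule for named genes and alternatives were fixed before the data were examined. The named genes were Notch1, every measured Notch target, the 8 largest rises and 8 largest falls among changed genes whose groups did not overlap (placeholder, microRNA and chemosensory receptor symbols excepted), and up to 3 changed members of each other list with the smallest adjusted p, or the 1 with the smallest p where none changed. This gave 79 genes. Other list members are named as examples of their list. The alternatives were the replicate number as a block, median centring, a second quantile normalisation, leaving out the dimmest 30% of genes, an intensity trend with a robust prior, the brightest probe set per gene, array weights, all probe sets, a stricter threshold of 0.01, a minimum absolute log2 fold change of 1, and leaving out each array in turn.

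The scripts were tested on simulated data for the comparison of NICD1 with control over 18166 genes. Independent normal noise was drawn for each gene, and 67 genes were given a log2 change of 0.5, 67 of 1 and 66 of 2. Of the genes given 0.5, 77.6% were recovered, and 100% of those given 1 or 2. In the measured data 14.7% of genes changed, so recovery there may differ. Of 194 calls, 9 were false. Among 200 unchanged simulated lists camera called 3 at an unadjusted p under 0.05, and it called 20 of 20 lists shifted by 0.3 on the log2 scale. Because these genes were drawn independently, this could not test the preset correlation. Estimated correlations in the measured lists reached 0.41, for cholesterol synthesis. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels and values gave no batch, slide or date, and a batch could not be examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.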

Results

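Gene expression was measured in NRK-52E cells, an epithelial line from rat kidney tubules, on 3 arrays of control cells and 3 arrays of cells carrying an overexpressed Notch1 intracellular domain (NICD1), the part of the receptor that acts in the nucleus after cleavage. The expression vector was pINDUCER21, and what the control cells carried, and whether either group received an inducer, is not given in the sources used here. The comparison asks which transcripts differ when this domain is overexpressed. Median linear intensity per array ranged from 57.5 to 60.1. Pearson's r of log2 intensity across probe sets, which are not independent replicates, was 0.993 to 0.995 within control, 0.993 to 0.994 within NICD1 and 0.989 to 0.991 between groups. The first principal component held 64.7% of the variance and separated the groups. The second held 11.8% and set control replicate 1, at 16.2, apart from control replicates 2 and 3, at -7.35 and -8.99.

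Notch1 and most measured Notch targets were higher in NICD1 cells. Notch1 (Entrez gene 25496) rose by 0.66 on the log2 scale (SE 0.081), 1.57-fold, from 8.52 ± 0.13 in control to 9.18 ± 0.08 in NICD1 cells (SD, n = 3 each; limma adjusted p = 0.00181). Its exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 allow. The species of the construct and the position of the Notch1 probes are not given in the sources used here, so whether this value includes the introduced domain stays open.

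Of 12 measured Notch targets, 8 rose, 0 fell and 4 did not pass over all genes, and 9 changed when adjusted over the list alone. Hey1, a transcriptional repressor induced by Notch, rose by 3.42 (SE 0.135), 10.7-fold, from 6.58 ± 0.29 to 9.99 ± 0.06 (SD, n = 3 each; limma adjusted p = 1.48e-05). Its relative Hey2 rose by 2.58 (SE 0.100). The receptor Notch3 rose by 2.45 (SE 0.083), and Jag1, a Notch ligand, rose by 1.87 (SE 0.076). Smaller rises were measured for Hes2 (0.96), Hes1 (0.89), Myc (0.52) and Nrarp (0.47), of which Hes2 and Nrarp lay below the background level in control. Hes7 (0.09), Hes5 (0.05), Heyl (-0.10) and Ccnd1 (-0.18) did not pass, Hes5 lay below background in both groups, and its value was -0.09 without NICD1 replicate 1. The call of Nrarp was lost without control replicate 2, and Ccnd1 fell under median centring, without the dimmest genes and with an intensity trend. The list passed camera upward (limma, Benjamini-Hochberg adjusted p = 1.04e-05; median log2 change 0.70), and its adjusted p = 0.167 with an estimated correlation.

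**Figure D1:**
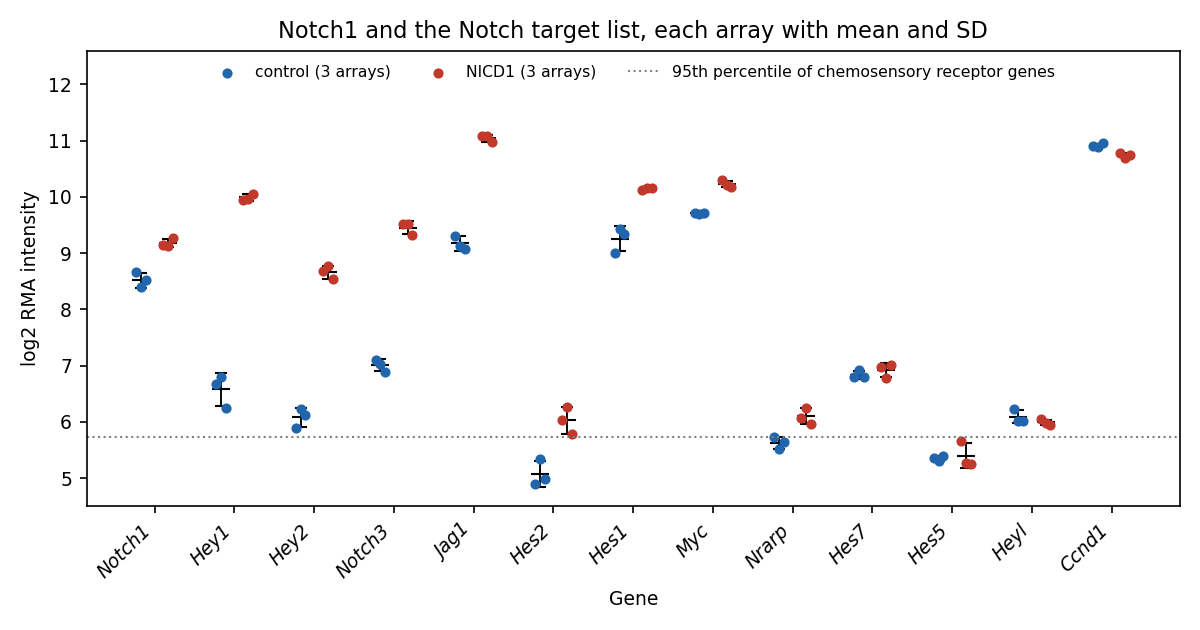
Log2 RMA intensity of Notch1 and the 12 measured Notch targets on each array, with control in blue, NICD1 in red, black bars for the mean and SD of 3 arrays, and a dotted line at the background level of 5.74. Hey1 lies near 6.58 in control and 9.99 in NICD1 cells, whereas the groups of Hes5, Hes7 and Heyl overlap.

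Of 18166 genes tested, 2666 (14.7%) changed, 1354 upward and 1312 downward (limma, Benjamini-Hochberg), and 277 of them by at least 1 on the log2 scale, 166 upward and 111 downward. The groups did not overlap for 5950 genes (32.8%), where chance gives 10%. Of the changed genes, 181 lay below background in both groups.

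The 8 largest rises included secreted, adhesion and cytoskeletal genes. Selp (Entrez gene 25651), which encodes the adhesion receptor P-selectin, rose by 4.51 (SE 0.088), 22.8-fold, from 7.14 ± 0.17 to 11.65 ± 0.02 (SD, n = 3 each; limma adjusted p = 1.98e-06). Rap1gap2, a GTPase-activating protein for Rap1, rose by 3.61 (SE 0.080), and Olfml2a, an extracellular olfactomedin-domain protein, by 3.18 (SE 0.063). The tight junction claudin Cldn19 rose by 2.87 (SE 0.231), from a control level of 5.80 ± 0.51 near the background of 5.74, with control replicates 2 and 3 below it. The keratin Krt14 rose by 2.62 (SE 0.053) and the interleukin-6 family cytokine Clcf1 by 2.56 (SE 0.068). Hey1 and Hey2 completed this group.

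The 8 largest falls included signalling and transcription factor genes. Tlr1 (Entrez gene 305354), a receptor for bacterial lipopeptides, fell by 3.14 on the log2 scale (SE 0.110), from 8.22 ± 0.07 to 5.08 ± 0.22 (SD, n = 3 each; limma adjusted p = 1.01e-05), and its NICD1 level lay below background. Scx, a basic helix-loop-helix factor of tendon, fell by 2.73 (SE 0.108), and Edn1, the precursor of the vasoconstrictor endothelin, fell by 2.61 (SE 0.056). Dab2, an endocytic adaptor of the proximal tubule, fell by 2.34 (SE 0.071). The other falls were those of Slc24a3 (-2.15), Foxp2 (-2.08), Cd34 (-1.95) and Atoh8 (-1.94).

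**Figure D2:**
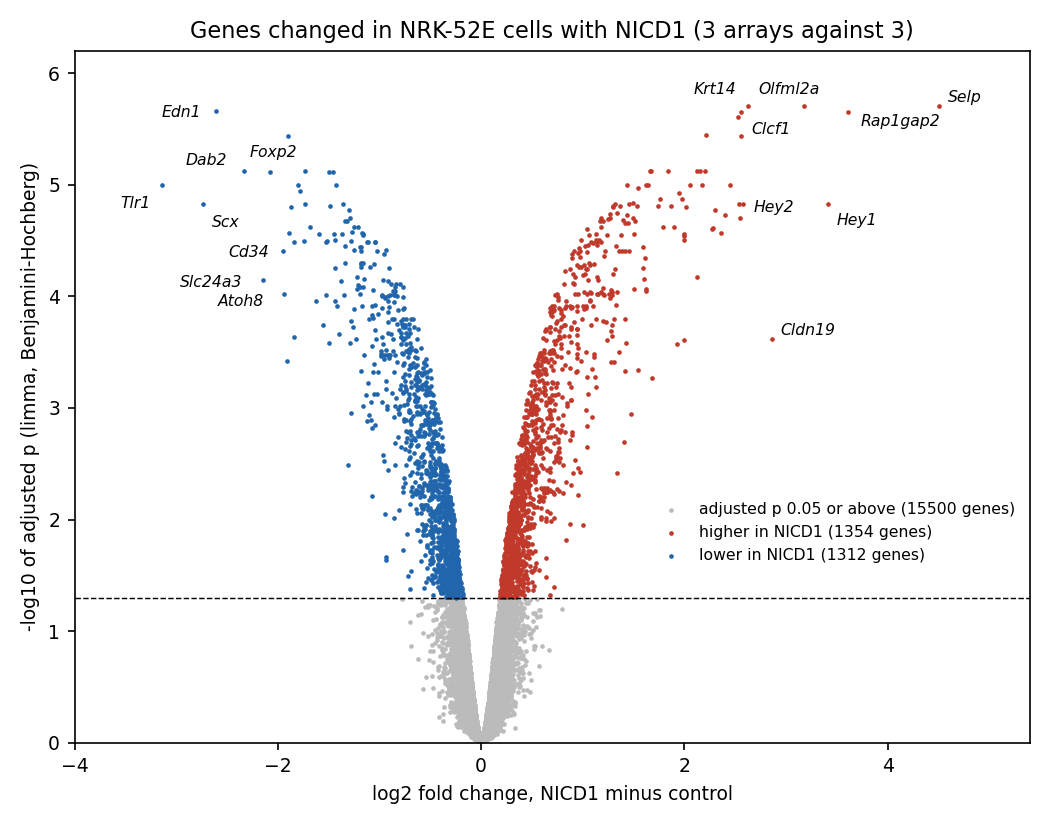
Log2 fold change of each gene (NICD1 minus control, 3 arrays each) against -log10 of its limma adjusted p, with the 1354 genes that rose in red, the 1312 that fell in blue and the threshold of 0.05 dashed. Labels mark the 8 largest rises and falls, from Selp at 4.51 to Tlr1 at -3.14.

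Mesenchymal and matrix genes rose more often than they fell. Of 31 measured, 16 rose, 3 fell and 12 did not pass, and 20 changed when adjusted over the list alone. The matrix protein Postn rose by 2.15 (SE 0.066), Tgfb1 by 1.30 (SE 0.053) and fibronectin, Fn1, by 0.90 (SE 0.049), from 10.98 ± 0.03 to 11.88 ± 0.02 (SD, n = 3 each). The transcription factors Twist2 (1.33), Snai1 (1.27) and Zeb2 (0.88, control below background) and the cadherin Cdh2 (1.32) also rose. S100a4 (-0.65), Lox (-0.52) and Ccn2 (-0.40) fell, and Vim (0.07) and Tagln (-0.09) did not pass. The list passed camera upward (limma, Benjamini-Hochberg adjusted p = 7.05e-05; median 0.28), with adjusted p = 0.167 with an estimated correlation.

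Epithelial junction genes did not move together. Of 33 measured, 3 rose and 3 fell, 6 changed when adjusted over the list alone, and 17 lay above background in at least 1 group. The keratin Krt8 rose by 1.08 (SE 0.055), plakoglobin, Jup, by 0.50 (SE 0.066) and the desmosomal Pkp2 by 0.33 (SE 0.054). The tight junction genes Cgn (-0.31), F11r (-0.29) and Tjp1 (-0.26) fell, while Cdh1, below background in both groups, had a value of -0.06. The count of falls was 0 without NICD1 replicate 1 or NICD1 replicate 3, and 1 without control replicate 3 or NICD1 replicate 2. The list did not pass camera (limma adjusted p = 0.734).

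More genes of glycolysis rose than fell. Of 16 measured, 10 rose, 2 fell and 4 did not pass, and 12 changed when adjusted over the list alone. The phosphofructokinase Pfkp rose by 1.98 (SE 0.075), from 7.46 ± 0.12 to 9.44 ± 0.06 (SD, n = 3 each), the hexokinase Hk2 by 1.13 (SE 0.055) and the enolase Eno2 by 1.06 (SE 0.054). The lactate transporter Slc16a1 (-0.62) and the phosphofructokinase Pfkm (-0.27) fell. Camera called the list upward (limma, Benjamini-Hochberg adjusted p = 0.000256; median 0.35), with adjusted p = 0.452 with an estimated correlation.

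More genes of cholesterol synthesis fell than rose. Of 20 measured, 10 fell, 2 rose and 8 did not pass, and 16 changed when adjusted over the list alone. The sterol sensor Insig1 (-1.09), the squalene synthase Fdft1 (-0.95, SE 0.083) and the isomerase Idi1 (-0.71) fell. Hsd17b7 rose by 0.94 (SE 0.073) and Insig2 by 0.50 (SE 0.052). The list mean was 9.30 on control replicate 1, which stood apart above, and 9.18 and 9.09 on control replicates 2 and 3, against 8.93 to 8.94 in NICD1 cells. The count of falls was 6 without NICD1 replicate 2 or NICD1 replicate 3. Camera called the list downward (limma, Benjamini-Hochberg adjusted p = 0.000477; median -0.26), with adjusted p = 0.547 with an estimated correlation.

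In the unfolded protein and amino acid response list, 9 of 27 measured genes rose, 2 fell and 16 did not pass, and 13 changed when adjusted over the list alone. The lipoprotein receptor Vldlr rose by 1.59 (SE 0.083), the cystine transporter Slc7a11 by 1.42 (SE 0.132) and the pseudokinase Trib3 by 1.10 (SE 0.076). The chaperones Hspa5 (0.03) and Hsp90b1 (-0.03) did not pass, and the endoplasmic reticulum proteins Sdf2l1 (-0.39) and Pdia6 (-0.27) fell. The count of falls was 1 without control replicate 3 or without any 1 of the NICD1 replicates. The list passed camera upward (limma, Benjamini-Hochberg adjusted p = 0.00898; median 0.12), with adjusted p = 0.380 with an estimated correlation.

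Few cell cycle or oxidative phosphorylation genes changed. Of 45 cell cycle genes, 1 fell, the kinesin Kif23 (-0.25, SE 0.063), and 0 changed when adjusted over the list alone, with 4 falls and 1 rise at an unadjusted p under 0.05 in limma. Mki67 (-0.09) and Top2a (-0.07) did not pass. The list passed camera downward (limma, Benjamini-Hochberg adjusted p = 0.0298; median -0.07), with adjusted p = 0.254 with an estimated correlation. That call ended without control replicate 2 (0.0834), NICD1 replicate 1 (0.0889) or NICD1 replicate 3 (0.0594), after a second quantile normalisation (0.0837) and without the dimmest genes (0.0679). The falls numbered 0 without any array except control replicate 1, 3 without control replicate 1, 3 without the dimmest genes, 2 with array weights, and 5 beside 1 rise with an intensity trend.

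Of 31 oxidative phosphorylation genes, 2 fell, Ndufb10 (-0.27, SE 0.068) and Sdha (-0.20, SE 0.050), and 0 changed when adjusted over the list alone, with 5 falls and 0 rises at an unadjusted p under 0.05 in limma. Leaving out any 1 array left 0 falls, and an intensity trend gave 4. By camera the list passed downward (limma, Benjamini-Hochberg adjusted p = 0.0443; median -0.07), with adjusted p = 0.678 with an estimated correlation. The list mean was 10.36 on control replicate 1, against 10.48 and 10.50 on the other controls and 10.35 to 10.42 in NICD1 cells. The call ended without control replicate 2 (0.142), control replicate 3 (0.257), NICD1 replicate 2 (0.139) or NICD1 replicate 3 (0.0820), after a second quantile normalisation (0.0816), without the dimmest genes (0.0818) and with fry (0.181). Ribosomal protein genes, a second abundant group, had 0 of 27 changed by limma, and 0 when adjusted over the list alone, with 0 rises and 2 falls at an unadjusted p under 0.05, Rps14 having a value of -0.14 (camera adjusted p = 0.507). In that list 1 gene rose without control replicate 3, and Rps14 fell with an intensity trend.

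Notch pathway components changed in both directions. Of 29 measured, 8 rose and 4 fell, and 17 changed when adjusted over the list alone. Lfng, a glycosyltransferase acting on Notch receptors, fell by 1.18 (SE 0.110), the presenilin Psen2 fell by 0.79 and the ubiquitin ligase gene Neurl1 rose by 0.79 (SE 0.082). The rises numbered 3 without NICD1 replicate 1, 4 without control replicate 2, and 5 without control replicate 3 or NICD1 replicate 2. The falls numbered 2 without any array except control replicate 3, and 7 beside 10 rises with an intensity trend. The list did not pass camera (limma adjusted p = 0.256).

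The lists of TGF-beta, BMP and Hippo targets and of Wnt targets were also split. Of 23 TGF-beta, BMP and Hippo targets, 8 rose and 6 fell, and 16 changed when adjusted over the list alone. Fjx1 rose by 2.40 (SE 0.103) and Ankrd1 by 1.16 (SE 0.058), while Smad6, an inhibitor of BMP signalling, fell by 0.86 (SE 0.063). Of 21 genes in the Wnt list, which holds ligands and secreted inhibitors beside targets, 3 rose and 5 fell. Adjusted over that list alone, 9 changed. The ligands Wnt4 and Wnt5a rose by 2.20 (SE 0.070) and 0.97 (SE 0.052), and Apcdd1 fell by 0.76 (SE 0.087). The Wnt falls numbered 1 without NICD1 replicate 1, 2 without control replicate 2, control replicate 3 or NICD1 replicate 2, and 3 without control replicate 1. Neither list passed camera (limma adjusted p = 0.756 for both). With fry both passed upward (adjusted p = 0.0305 for TGF-beta, BMP and Hippo, and 8.21e-05 for Wnt). The median and mean differed in sign for both lists (-0.03 and 0.14, and -0.03 and 0.05), and camera's direction was down for the Wnt list where fry's was up.

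Inflammatory genes comprised 8 rises and 4 falls among 34 measured, and 14 changed when adjusted over the list alone. Tnfaip2 rose by 0.91 (SE 0.056), the chemokine Ccl2 by 0.83 and Il6, below background in both groups, by 0.68. The growth factor Csf1 fell by 1.05 (SE 0.072), and Il33 fell by 0.98 (SE 0.069) to a level below background. In the interferon list 2 of 31 rose, Oas1a (0.52, SE 0.130) and Herc6 (0.46, SE 0.093; control below background), and 0 changed when adjusted over the list alone, with 10 rises and 0 falls at an unadjusted p under 0.05 in limma. The call of Oas1a was lost without any 1 of the controls. The interferon count was 1 without control replicate 3, 7 without the dimmest genes, 6 with an intensity trend and 5 with array weights. Neither list passed camera (limma adjusted p = 0.150 and 0.0737), although the interferon list passed with array weights (0.0498) and without control replicate 1 (0.0403). Both lists passed upward with fry (adjusted p = 0.00479 and 0.0305).

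Among NRF2 targets 6 of 26 rose and 2 fell, and 13 changed when adjusted over the list alone. The aldehyde dehydrogenase Aldh3a1 rose by 1.03 (SE 0.113), Osgin1 by 0.70 (SE 0.068) and the glutathione transferase Gsta4, below background in control, by 0.68 (SE 0.077), while Nqo1 (0.28) did not pass. Among p53 targets and CDK inhibitors 2 of 19 rose and 3 fell, and 5 changed when adjusted over the list alone. The BH3-only gene Pmaip1 rose by 0.75 (SE 0.061), the CDK inhibitors Cdkn2c and Cdkn1b fell by 0.71 (SE 0.053) and 0.37 (SE 0.054), and Cdkn1a had a value of -0.04. Neither list passed camera (limma adjusted p = 0.116 and 0.265), although the NRF2 list passed without control replicate 3 (0.0467). Its rises numbered 9 with an intensity trend, beside 4 falls, and 9 without the dimmest genes, beside 2 falls. The NRF2 list also passed upward with fry (adjusted p = 0.0123), whereas the list of p53 targets and CDK inhibitors did not (0.0568).

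Few proximal tubule genes were measurable above background. Of 29 measured, 8 lay above it in at least 1 group, 0 rose and 5 fell, and 5 changed when adjusted over the list alone. Besides Dab2, the amino acid transporter subunit Slc7a9 fell by 0.44 (SE 0.068) and the peptidase gene Anpep by 0.26 (SE 0.051), the latter below background in both groups. The falls numbered 2 without NICD1 replicate 1, and 3 without control replicate 2 or NICD1 replicate 2, and in all 3 cases, and with an intensity trend, the call of Anpep was lost. In the tubule injury and repair list 7 of 28 rose and 5 fell, and 15 changed when adjusted over the list alone. The transcription factors Sox4 and Klf6 rose by 0.90 (SE 0.054) and 0.81 (SE 0.065), and the receptor Met fell by 0.66 (SE 0.051). The injury markers Havcr1 (-0.14, below background in both groups) and Lcn2 (-0.20) did not pass. The falls of this list numbered 3 without any array except control replicate 1. Neither list passed camera (limma adjusted p = 0.129 and 0.401). With fry the proximal tubule list passed downward (adjusted p = 0.0104) and the injury and repair list upward (0.00519).

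Markers of other cell types showed few changes. Of 14 leukocyte markers Cd68 rose (0.27, SE 0.059), and of 12 endothelial markers Flt1 rose (0.35, SE 0.085) below background and Tek fell (-0.57, SE 0.077). Of 7 podocyte markers Wt1 rose (0.55, SE 0.050). Of 20 distal nephron markers Aqp3 rose (1.33, SE 0.193), Calb1 rose below background (0.29, SE 0.060) and Gata3 fell (-0.77, SE 0.062). Of 13 fibroblast and pericyte markers Mfap5 (-0.85, SE 0.058) and Fbln1 (-0.34, SE 0.073) fell. Adjusted over the list alone, 1, 2, 1, 3 and 3 markers changed in that order. Among the fits that left out 1 array, the rise of Cd68 was kept only without control replicate 1 and that of Flt1 only without NICD1 replicate 1. In those fits the rise of Calb1 was kept only without control replicate 1 or NICD1 replicate 3, and it did not pass with an intensity trend. The fall of Fbln1 was lost without control replicate 2 or NICD1 replicate 2. With an intensity trend 2 leukocyte markers rose and 1 podocyte marker fell, and with it, with array weights or without the dimmest genes 1 fibroblast or pericyte marker rose. None of these 5 lists passed camera (limma adjusted p from 0.756 to 0.827). Of the 5, only the fibroblast and pericyte list passed with fry, downward (adjusted p = 0.0436). Median, mean and camera direction differed in sign for endothelial (0.04, -0.01, down), podocyte (-0.08, 0.005, down) and fibroblast markers (0.01, -0.02, down).

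**Figure D3:**
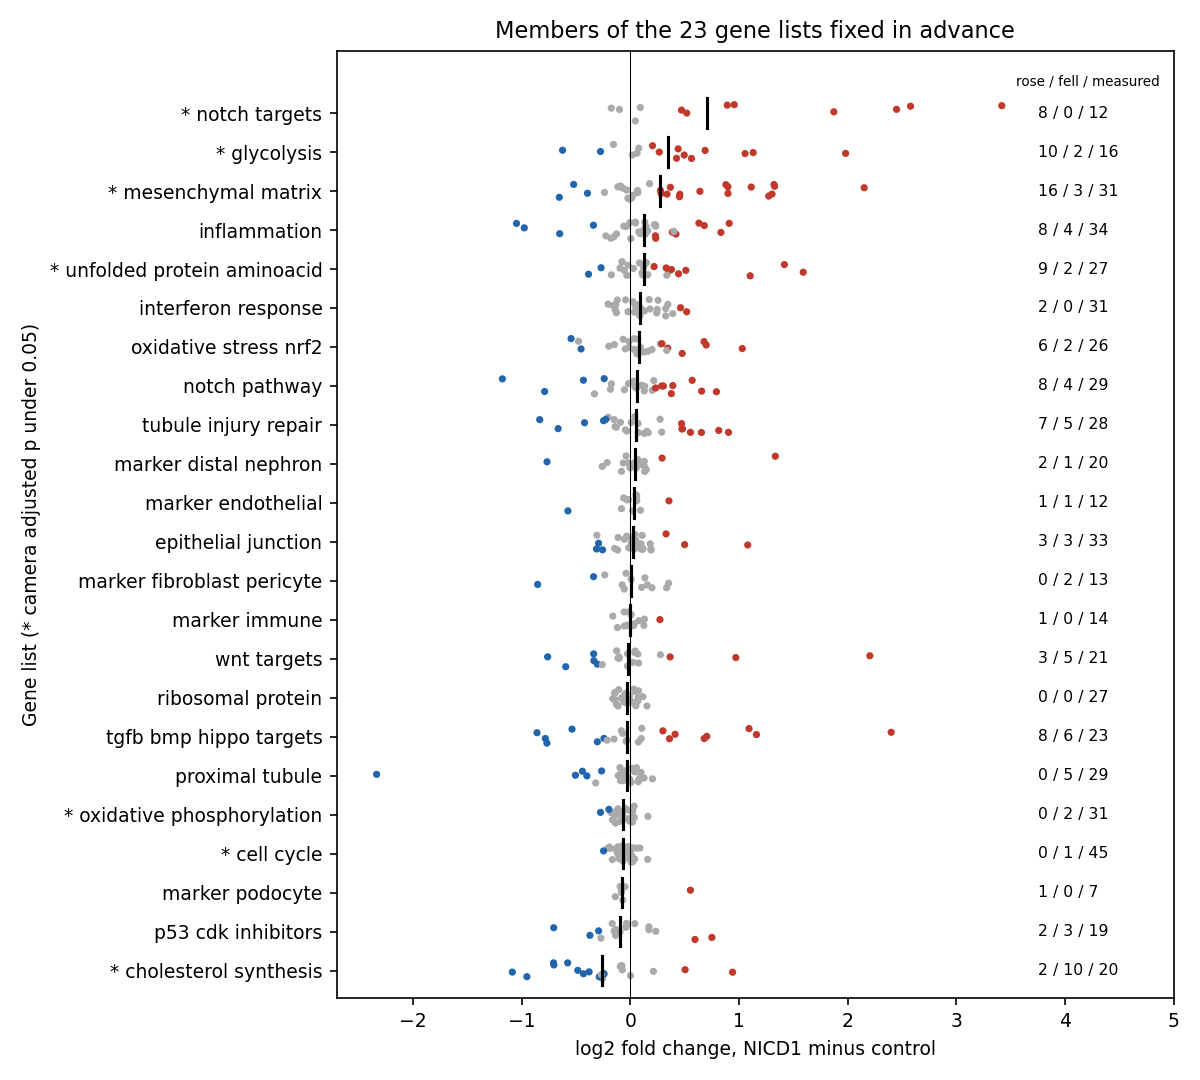
Log2 fold change (NICD1 minus control, 3 arrays each) of every measured member of the 23 gene lists, with genes that rose in red, genes that fell in blue, others in grey, and a black bar at the list median. Medians run from 0.70 for Notch targets to -0.26 for cholesterol synthesis, and asterisks mark the 7 lists that passed camera with the preset correlation. With an estimated correlation 0 lists passed.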

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

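No test in this part was chosen only after the result was seen. Of 17599 probe sets with no gene symbol in the annotation, which entered no comparison of genes or lists above, 222 rose in NICD1 cells and 157 fell (limma over all probe sets, Benjamini-Hochberg). Probe set 17881665 rose by 5.12 on the log2 scale (SE 0.110), from 6.84 ± 0.21 to 11.96 ± 0.01 (SD, n = 3 each), and 17881663 rose by 3.96 (SE 0.084). Probe sets 17880847 and 17882747 fell by 2.37 and 2.04. Their transcripts are not identified here.

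The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2666 changed genes and the highest of the others 0, and only the real split itself reached its count. For the lists passing camera the values were 7 and 3, and for changed list members 158 and 0, again with only the real split as large. Every other split mixes the groups, so the group difference widens its spread and lowers its counts. The counts of the other splits are therefore no chance level for the real one.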

How the results depend on the processing

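All alternatives here were planned. The number of changed genes lay between 1919 and 3571 over the other model, scaling and probe set settings, was 1473 at an adjusted p under 0.01 and 277 with an absolute log2 change of at least 1, both by construction subsets, and 1830 to 2486 when 1 array was left out. Median centring gave 1164 rises and 1518 falls and moved the median log2 change of all genes from 0.007 to -0.02. With the replicate number as a block 1919 genes changed, of which 1857 were shared, 6 lists passed, 66 named genes changed and 127 list members changed; the lost calls were those of the oxidative phosphorylation list and of Nrarp, Anpep, Kif23, Herc6, Ndufb10, Sdha, Cd68 and Flt1. Residual correlations of arrays with the same number were -0.03, -0.01 and -0.01, so the numbers gave no sign of pairing and not every array correlated best with its own number. Notch1 stayed at an adjusted limma p under 0.05 with the block, in the scaling, filter, prior, probe set and weight settings and without each array, at 0.59 to 0.72 without 1 array, and 0.66 with the block. Lists passing numbered 5 to 8 without 1 array, 0 with an estimated correlation and 14 with fry, 10 upward and 4 downward. Fry does not compare a list with other genes and so asks another question. Why the calls ended with an estimated correlation was not tested, but a larger correlation does not account for all of them. For cell cycle genes the estimate was -0.0075, under the preset 0.01, yet the unadjusted camera p rose from 0.00778 to 0.0331. In the other lists that passed, the estimates lay above the preset, from 0.019 for mesenchymal and matrix genes to 0.41 for cholesterol synthesis. Changed list members numbered 114 to 149 and changed named genes 64 to 70 without 1 array, against 158 and 74. Hes5 ranged from -0.085 without NICD1 replicate 1 to 0.12, below background in both groups. Signal limits the rest: 11416 of 18166 genes lay above background in at least 1 group.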

Other observations

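The tests of endothelial and leukocyte markers, both Tlr1 tests, the tests of gene families and of neighbouring genes, and the semaphorin, ERBB, interleukin-1 receptor, keratin and laminin, Hox and Toll-like receptor groups were chosen only after the result was seen. Class 3 semaphorins, secreted guidance factors, included 0 rises and 5 falls among 7 measured, with Sema3c at -1.43 (SE 0.051) and Sema3d at -1.17 (SE 0.056). Among 15 ligands and receptors of the ERBB family 4 rose and 5 fell. Tgfa (0.92, SE 0.069) and Egfr (0.47, SE 0.056) rose, whereas Btc (-1.62, SE 0.110), Nrg1 (-1.60, SE 0.077) and the receptor Erbb3 (-1.02, SE 0.105) fell. Among 15 genes of the interleukin-1 receptor family and its ligands 5 rose and 1 fell. The receptor for interleukin 33, Il1rl1, rose by 2.36 (SE 0.112) from a control level below background, and its partner Il1rap by 1.62 (SE 0.056), while the ligand Il33 fell by 0.98 (SE 0.069) to a level below background.

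Of 9 genes of basal keratins, basement membrane laminin and their partners 4 rose and 0 fell. The rises were those of Krt14 (2.62), Krt17 (2.28), Lama3 (1.18) and Lamb3 (1.17). Itgb4 (-0.34), Itga6 (-0.07), Krt15 (-0.06), Col17a1 (-0.02) and Tp63 (0.13) did not pass, with Krt15, Col17a1 and Tp63 below background in both groups. Of 31 protein-coding Hox genes, not counting the antisense transcript Hoxa11-as, which fell by 0.41, 2 rose and 8 fell, with Hoxa13 at -1.53 (SE 0.078) and Hoxd10 at -1.05 (SE 0.053). Over gene families defined by symbol, 0 of 402 one-sided Fisher's exact tests passed after Benjamini-Hochberg adjustment and 20 had an unadjusted p under 0.05. The lowest adjusted p was 0.0740, for 7 falls among 13 Aldh genes. Fold changes of genes next to each other on the genome correlated at 0.10 across 11199 genes, which are not independent replicates, and the highest of 1000 permutations gave 0.037 (permutation p = 0.001, the smallest they can give).

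Selp rose by 4.51 in an epithelial line, and cells that carry P-selectin could be a source. The median log2 change was 0.0355 over 12 endothelial markers (95% bootstrap interval from 10000 draws of genes -0.05 to 0.06), 0.000888 over 14 leukocyte markers (-0.04 to 0.08) and 0.0632 over 7 platelet markers (-0.05 to 0.10). These medians argue against endothelial cells, leukocytes or platelets in the NICD1 cultures. The intervals measure the spread between genes, which are not independent replicates, and not the spread between arrays. NICD1 levels of the brightest markers were 7.09 for Tek, 11.32 for Cd14 (11.19 in control) and 6.43 for Treml1, and 2, 6 and 3 of the markers lay above background. Transcription in the NRK-52E cells themselves, under NICD1 or through another difference between the cultures, stays open and was not tested.

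Of 11 Toll-like receptor genes 4 fell, Tlr1 (-3.14), Tlr6 (-1.91), Tlr10 (-0.98) and Tlr5 (-0.70), and 1 rose, Tlr2 (0.23), below background in both groups, and the NICD1 levels of Tlr1 and Tlr10 lay below background. For the joint fall of Tlr1 and Tlr6, a shared probe signal or a lost chromosome segment could be a source. The fold change of Tlr1 minus that of Tlr6 was -1.23 (95% interval -1.74 to -0.72). The NICD1 level of Tlr1 lay below background, however, and no background was measured for each probe set. The difference therefore does not decide whether Tlr1 probes read Tlr6 transcripts, or the converse, and the 2 cannot be told apart. The 20 nearest measured genes above background, with Toll-like receptor genes left out, had a median of -0.16 (95% bootstrap interval over genes -0.19 to 0.02). By the adjusted limma test 1 rose and 3 fell, which argues against loss of a segment spanning most of them. Of the nearest gene on each side, Klf3 fell (-0.65) and Klhl5 (-0.20) did not pass. On the side of Klhl5 values ran from -0.71 (Smim14) to 0.006 (Lias), and on that of Klf3 from -1.25 (Pcdh7) to 0.65 (Rell1). The median, taken over both sides, cannot decide about a partial loss on 1 side or a segment that reaches only the next gene. A change limited to the Toll-like receptor genes, or reaching a nearest neighbour or part of 1 side, in sequence or in regulation under NICD1, stays open.

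Of 16 glycolysis genes 10 rose and 2 fell. The list passed camera with the preset correlation (limma adjusted p = 0.000256) but not with an estimated one (adjusted p = 0.452, unadjusted p = 0.119). For the rises a response to low oxygen is a candidate explanation. A list of targets of the hypoxia-inducible factor outside glycolysis was written before its values were seen. Its median was 0.49 over 18 genes (95% bootstrap interval over genes 0.15 to 0.66), with 12 rises and 1 fall, Car12, to a level below background. It passed camera upward (unadjusted limma p = 9.17e-08, and p = 0.00737 with an estimated correlation). As it was tested alone, these p-values are not comparable with those adjusted over the 23 lists. Vegfa rose by 0.69 and Kdm3a by 0.70, whereas Adm (-0.03) and Egln3 (-0.05, below background) did not pass. A single deviating array is argued against, since the smallest mean shift of the glycolysis list without 1 array was 0.37 of a full 0.40, and the median of the hypoxia-inducible factor targets then stayed between 0.42 and 0.51. Whether oxygen or density differed between the cultures, or NICD1 acts on these genes, stays open, as no label gives either.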
